A study of Mycolicibacterium smegmatis with 6 samples.

How the data were processed

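RNA sequencing libraries of Mycolicibacterium smegmatis, 3 with plasmid-borne ydeH and 3 with ydeH(E208,209A), were compared from 1 deposited table. Samples were assigned to groups and replicate numbers by their titles, and table columns to samples by the column names given in the sample descriptions. The column names of the mutant libraries read as wild type, while the titles give the mutant plasmid, and the titles were followed. The labels' extraction protocol speaks of retinal tissue, which is not the organism of the series, so it was not used. Per the submitters' processing notes Bowtie2 was used, with its version and role not given in the sources used here. The counting tool and its strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

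The table holds deposited read counts per gene, whole numbers per the file headers, and FPKM values that the authors computed from them. The deposited FPKM equal the count per kilobase of gene span, scaled to the library's summed gene counts, with a largest relative difference of 0.0011 in any library. FPKM are therefore shares of all counted reads and fall in every other gene when some genes rise. Of 6938 genes, 122 had a count of 0 in all libraries. They include 2 blocks of 56 genes each, MSMEG_1003 to MSMEG_1058 and MSMEG_2283 to MSMEG_2338, of 53.2 kb each, at equal span, so genes of these blocks are not analysed here. Total counts ranged from 7147023 to 11559878 per library, and 77.6% to 93.3% of genes held at least 100 counts. The 10 largest genes took 6.4% to 10.3% of counts. Chi-square per degree of freedom over genes was 3.82 to 11.4 between libraries of 1 group and 224 to 306 between groups, so every pair of replicates differed by more than sampling noise.

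Genes carry locus tags of strain MC2 155. Tags were given as names for 6132 genes, taken from the reference gene table of assembly ASM1500v1 by coordinate for 800, on a chromosome of the same name, and left as the symbol for 6. Symbols come from the table or from that reference.

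Because the table held counts, the planned count test replaced limma on FPKM as the main test. Counts were analysed with R 4.3.3 and edgeR 4.0.16: filterByExpr kept 6768 genes, libraries were scaled by trimmed means of M values (TMM), and glmQLFit and glmQLFTest compared ydeH with the mutant with Benjamini-Hochberg adjustment at 0.05. A 2-fold change is a log2 fold change of at least 1 in size. The SE is the fold change divided by the square root of the quasi-likelihood F. TMM factors were 1.361 to 1.494 for ydeH and 0.680 to 0.734 for mutant libraries. The common biological coefficient of variation was 7.2%. No batch is given in the labels, so a batch that follows the groups could not be separated.

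Before the data were examined, 40 gene lists were fixed: 26 by locus tag and 14 by annotated product. By locus they were the DosR regulon, hydrogenases, peroxide, superoxide and thiol defence, siderophore and iron acquisition, ESX-1, ESX-3, the glycopeptidolipid locus, mycolic acid and fatty acid synthesis, arabinosyl transferases, mce4, sterol ring degradation, ATP synthase, NADH dehydrogenase type I, cytochrome bcc-aa3, cytochrome bd, heat shock and folding, nitrogen limitation, phosphate limitation, SOS repair, zinc limitation, WhiB7 response, glyoxylate and gluconeogenesis, arginine synthesis, Msp porins, c-di-GMP genes and toxin-antitoxin pairs. By product they were ribosomal proteins, ribosomal and transfer RNA, aminoacyl-tRNA synthetases, sigma and anti-sigma factors, PE and PPE, Mce, MmpL and MmpS, cytochrome P450, universal stress, TetR, WhiB, transposases and integrases, acyl-CoA dehydrogenases and ABC transporters. For 7 locus members the annotation named another function, and they were dropped. Lists were tested with limma 3.58.1 on log2 CPM with a prior count of 2, by camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. With the preset correlation 20 of 40 lists passed, and 16 to 19 in the other splits of the libraries. With an estimated correlation camera passed 0 lists, 2 of them at an unadjusted p under 0.05, and fry passed 37, without comparing a list with other genes. The genes named were fixed by rule: (a) the 10 largest log2 fold changes in each direction with adjusted p under 0.05, no overlap between the groups and a mean of at least 10 FPKM in the higher group; (b) by the same criteria, the 5 largest in each direction among genes with a symbol in the table and not in (a); (c) up to 4 changed members of each list that passed camera or had at least 3 changed members; (d) the 3 longest runs in each direction; (e) all genes of the c-di-GMP list; (f) ydeH itself if present. For (c) at most 3 members per list are given, and for lists that did not pass camera mostly counts. MSMEG_1677, MSMEG_1679 and MSMEG_0062, and the runs after subtraction, were chosen after their values were seen. Runs are 4 or more consecutive tested genes in chromosome order that changed in 1 direction, compared with 1000 random orders.

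An extra background in the ydeH libraries was estimated after the data were seen. In genes of at least 300 bases with 40 to 400 FPKM in the mutant, each ydeH library's FPKM was regressed on the mutant mean and the distance from the replication origin (robust regression weighted against strong genes, MASS 7.3.60.0.1), with the origin placed at the start of the chromosome. The intercept and the distance term were taken as an even background and subtracted from the counts, and genes with a mean of at least 100 FPKM were tested again. The fitted background was 78.3, 71.1 and 91.2 FPKM at the origin in ydeH replicates 1, 2 and 3, and 49.9, 45.4 and 57.4 FPKM at the terminus. It held 37.8%, 34.5% and 43.2% of counts. Genes with levels near this background have subtracted values that depend on the exact amount. Alternatives chosen with the test were no scaling factor, median-ratio factors, no filter, a filter at 5 FPKM, robust empirical Bayes, a replicate block, DESeq2 1.42.0, limma on log2(FPKM + 1), pseudocounts of 0.1 and 5, limma without trend, TPM, quantile normalization, runs of 3 or 6 genes, and leaving out each replicate. Added later were subtraction of 25% less or more background, drawing the same background into the mutant counts, the 2158 genes without correction, and thinning to the smallest library.

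The edgeR test was tested on simulated counts for 6759 genes of the comparison of ydeH with the mutant. It called 50 of 50 genes changed 2-fold up, 50 of 50 changed 4-fold up, 49 of 50 with a fold of 0.5 and 50 of 50 with a fold of 0.25, with 10 false calls. With an even background simulated in the ydeH libraries of the same comparison, 2010 unchanged genes were called at least 2-fold higher and 1336 lower. After subtraction, in 2002 genes, 0 unchanged genes were called 2-fold, and median log2 fold changes for the 4 fold sizes were 0.98, 1.99, -0.99 and -1.99. The simulated background was even, the form that the fit assumes, so good recovery was built in. That recovery does not show how subtraction fares in the real libraries, where the excess differed between levels of weak genes.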

Results

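RNA was sequenced from 6 libraries of Mycolicibacterium smegmatis, a fast-growing soil mycobacterium used as a laboratory model of its genus. The bacteria carried pMV261, an expression plasmid for mycobacteria, with ydeH, an Escherichia coli gene for a diguanylate cyclase, the type of enzyme that makes the second messenger c-di-GMP from GTP. In 3 libraries the plasmid held ydeH, and in the other 3 it held ydeH(E208,209A), the control, in which a pair of glutamates is replaced by alanine (called the mutant from here on). The table gave read counts and FPKM for 6938 genes. The counts summed to 11559878, 10692268 and 7147023 in ydeH replicates 1, 2 and 3, and to 10665621, 11372948 and 11240975 in mutant replicates 1, 2 and 3. The comparison asks which transcripts differ between bacteria with the cyclase and bacteria with the substituted enzyme. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries. The table names no ydeH or plasmid gene, so expression of the transgene was not checked in any library and is not analysed here.

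The genes that fell furthest with ydeH lay in a few loci. They were a cluster at MSMEG_1677 to MSMEG_1683, the ESX-3 secretion gene esxG, the porin gene mspA, the mycofactocin genes mftB and mftC, and genes of the region from MSMEG_3929 to MSMEG_3948. MSMEG_1683, a permease of the cytosine, purine and allantoin family, was at 117 ± 5.48 FPKM with ydeH and 616 ± 27.8 in the mutant (SD, n = 3 each). MSMEG_0620 (esxG) was at 178 ± 11.2 against 814 ± 8.40 FPKM. MSMEG_0965 (mspA), the main outer-membrane porin of this species, was at 737 ± 46.4 against 2860 ± 37.5 FPKM. The genes that rose furthest were weakly expressed. The 10 with the largest increase held 0.934 to 3.30 FPKM in the mutant and 16.6 to 54.9 FPKM with ydeH.

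By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6006 of 6768 tested genes changed, 3316 higher and 2690 lower with ydeH. Of these, 1811 were at least 2-fold higher and 1234 at least 2-fold lower. The direction depended on the scaling: with library totals alone 5221 were higher and 966 lower, 3732 and 93 of them at least 2-fold. Median-ratio factors gave 1246 at least 2-fold higher and 1565 lower. The median log2 fold change of all genes was 0.21 with the scaling used, 1.22 with library totals alone and 0.03 with median-ratio factors, so a fold change is relative to that median.

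Direction followed expression level. Genes at 10 to 20 FPKM in the mutant had a median of 14.8 FPKM there and 61.4 with ydeH, and 95.1% of the 1279 such genes were called higher. At 160 to 320 FPKM the medians were 214 and 205, and 99.8% of 576 genes were called lower. At 640 FPKM or more they were 1180 and 777, and all 324 genes, 100% of them, were called lower. Counts of changed list members, and camera's comparison with all other genes, therefore also follow the expression level of a list. The 10th percentile over genes was 35.2 to 41.3 FPKM in the ydeH libraries and 7.1 to 9.7 in the mutant libraries. In genes under 40 FPKM in the mutant, the median difference was 53.6 FPKM in the part of the chromosome nearest the replication origin and 34.4 FPKM in the part nearest the terminus, of 4 parts of equal distance range. Because of this shared increase, gene groups below with testable members are also given after a fitted even background was subtracted from the ydeH counts. That alternative was chosen after the data were seen and covers 2158 genes with a mean of at least 100 FPKM. After subtraction 68 genes were at least 2-fold higher and 120 at least 2-fold lower. Of the 1811 higher genes only 9 could be tested there, and 9 of the 68 were among the 1811. The 68 are therefore mostly other genes. Of the 1234 lower genes 1121 could be tested, and 117 of the 120 were among them. The same 2158 genes, tested and scaled on their own without any correction, gave 111 higher and 74 lower. Of the 111, 9 were among the 1811, and these were all of the 1811 that could be tested there. The small overlap of higher genes therefore follows from the limit of 100 FPKM. All 74 were among the 1234, so the number of lower genes fell without any subtraction too. Scaling on these genes alone is relative to their own shared level, so the share of the fall due to the background is left open. Of the 120 lower genes 47 were among those 74, and of the 68 higher genes 60 were among those 111. After subtraction 16 of 29 testable lists passed camera with a preset correlation, all of them lower (11 without correction, 10 of them lower), and 0 passed with an estimated correlation (lowest adjusted p = 0.19, 7 lists at an unadjusted p under 0.05). Before subtraction 20 of 40 lists passed with a preset correlation, and 16 to 19 passed in the other splits of the 6 libraries into 3 and 3, which mix the groups 2 to 1 and in which 0 genes changed (at most 3 at an unadjusted p under 0.05).

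**Figure D1:**
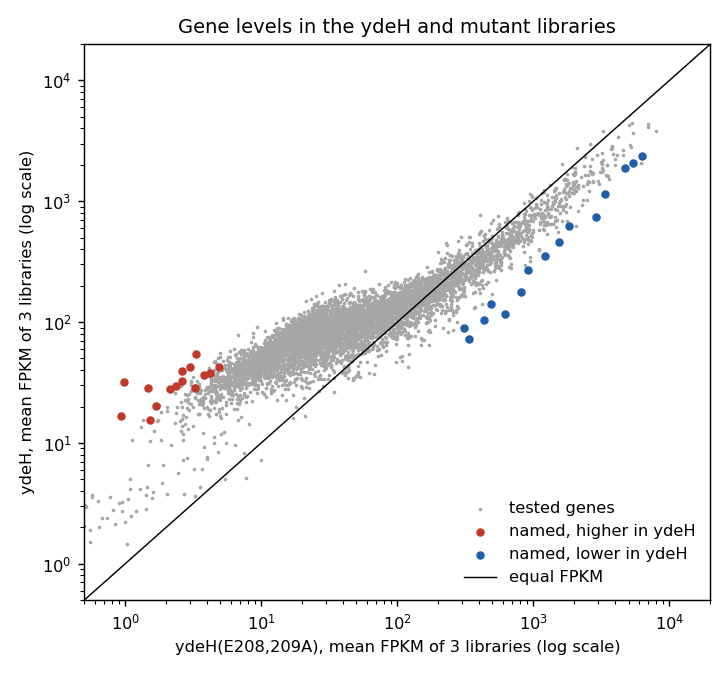
Mean FPKM of each tested gene in the 3 mutant libraries (horizontal) and the 3 ydeH libraries (vertical), both on log axes; red and blue points are genes named by the rules on fold change, and the line marks equal FPKM. Weak genes lie above the line, with medians of 14.8 and 61.4 FPKM at 10 to 20 FPKM in the mutant, and strong genes lie below it, with medians of 1180 and 777 FPKM at 640 FPKM or more.

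**Figure D2:**
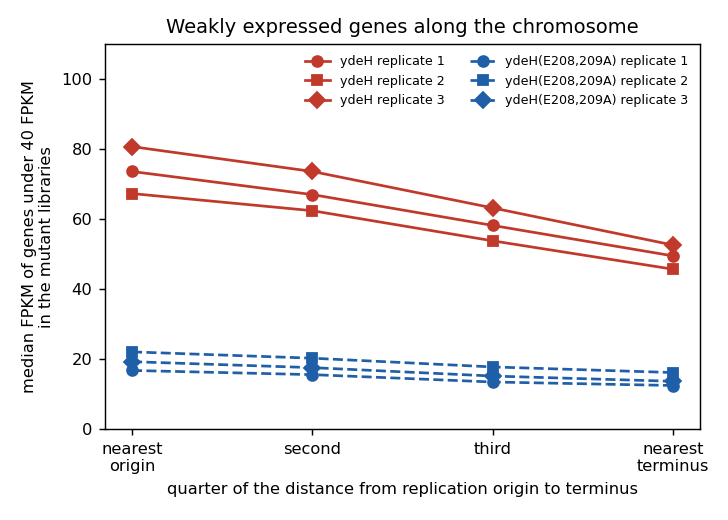
Median FPKM, per library, of genes under 40 FPKM in the mutant, in 4 ranges of distance from the replication origin to the terminus. The ydeH libraries lie between 67.3 and 80.7 FPKM near the origin and between 45.7 and 52.6 near the terminus, and the mutant libraries between 16.8 and 22.1 and between 12.5 and 16.2.

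The cluster at MSMEG_1677 to MSMEG_1683, at 1770884 to 1777435 on the chromosome (assembly ASM1500v1), fell as a block. MSMEG_1677 (aspA) encodes aspartate ammonia-lyase, which releases ammonium from aspartate. It was at 64.5 ± 3.96 FPKM with ydeH and 150 ± 6.09 in the mutant (SD, n = 3), a log2 fold change of -2.22 (SE 0.08, adjusted p = 7.4e-24). MSMEG_1683 had a log2 fold change of -3.40 (SE 0.10, adjusted p = 9.6e-26), MSMEG_1681, an endoribonuclease L-PSP family gene, of -3.21, and MSMEG_1682, a flavin-containing monooxygenase gene, of -3.08. MSMEG_1679, annotated as AmiB, and the unannotated MSMEG_1680 had -2.52 and -2.81. After background subtraction MSMEG_1683 was at -2.97 (SE 0.08) and MSMEG_1682 at -2.91. The ydeH level of aspA was near the background itself, and its subtracted value ran from -13.82 to -2.81 when the background was raised or lowered by 25%. That range was -5.67 to -3.37 for MSMEG_1681, -4.37 to -2.51 for MSMEG_1680, -5.07 to -2.36 for MSMEG_1679 and -3.52 to -2.56 for MSMEG_1682.

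**Figure D3:**
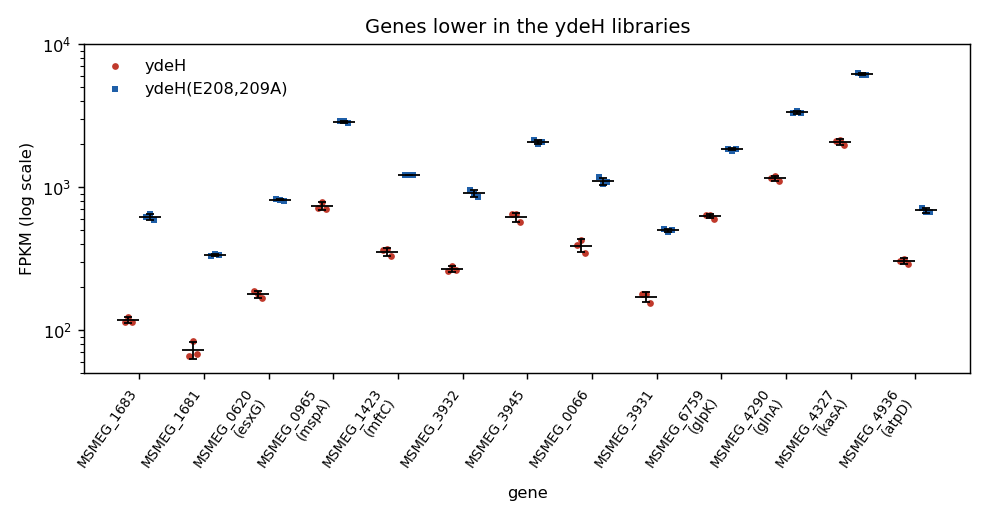
FPKM, on a log axis, of 13 genes that were lower with ydeH; each point is 1 library, and bars show the mean and SD of 3. The ydeH and mutant libraries do not overlap for any of the genes shown, as for MSMEG_0620 (esxG) at 178 ± 11.2 against 814 ± 8.40 FPKM.

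Genes of 2 type VII secretion systems fell. The list medians of ESX-3 and ESX-1 in the mutant were 141 and 136 FPKM, and 96.3% of all genes at 80 to 160 FPKM there were called lower. With ydeH the list medians were 122 and 107 FPKM, near the fitted background of 71.1 to 91.2 FPKM at the origin. Subtracted values of these lists therefore depend on its amount. ESX-3, which serves iron and zinc acquisition in mycobacteria, had 9 of 12 tested members lower and 3 higher, and the same 9 and 3 adjusted over the list alone. With library totals as the only scaling, 6 were lower and 5 higher. All 7 members testable after background subtraction were lower, with a median log2 fold change of -1.45. MSMEG_0620 (esxG) had -3.19 (SE 0.08, adjusted p = 4.3e-27) and -2.38 after subtraction, MSMEG_0621, its partner annotated as low molecular weight protein antigen 7, -2.56 and -2.05, and MSMEG_0624 (mycP3), the system's protease, -1.60 and -1.45. ESX-1, which secretes the EsxA and EsxB proteins, had 23 of 28 members lower and 3 higher over all genes and over the list alone, and 16 lower and 10 higher with library totals alone. After subtraction all 16 testable members were lower, with a median of -1.21. MSMEG_0066, annotated as the early secretory antigenic target, was at 391 ± 40.9 FPKM with ydeH and 1100 ± 58.7 in the mutant (log2 fold change -2.49, and -1.23 after subtraction). MSMEG_0065 beside it had -2.46 and -1.09, and MSMEG_0062 (eccCb), an ATPase of the system, -1.51 and -2.13 (-4.23 to -1.35 with 25% more or less background). The subtracted value of mycP3 ran from -2.07 to -1.09 in the same way. When background was instead drawn into the mutant counts, eccCb had -0.79, mycP3 -0.72 and esxG -1.77. Camera with a preset correlation placed both lists below other genes (adjusted p = 0.018 for ESX-3 and 1.6e-05 for ESX-1), with adjusted p = 0.43 for each with an estimated correlation. The PE and PPE list, whose family includes esxG in this annotation, had 5 of 10 higher and 5 lower, and all 4 of its testable members were lower after subtraction (camera's adjusted p = 0.035, and 0.21 with an estimated correlation).

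The DosR dormancy regulon, induced by low oxygen and nitric oxide in mycobacteria, had 17 of 18 members lower and 1 higher, over all genes and over the list alone, and the same counts with library totals alone. Its list median in the mutant was 1120 FPKM, and 100% of all genes at 640 FPKM or more there were called lower. After subtraction 15 of 17 were lower and 1 was higher, with a median of -0.56. MSMEG_3945, a universal stress protein gene, was at 618 ± 45.1 FPKM with ydeH and 2070 ± 54.9 in the mutant (log2 fold change -2.74, SE 0.11, adjusted p = 8.3e-22; -1.29 after subtraction). MSMEG_3932 had -2.76 and -1.51, and MSMEG_3942 had -2.57 and -1.26. The hydrogenase list had 16 of 24 members lower and 4 higher, but 13 higher and 8 lower with library totals alone. Of its 9 members testable after subtraction 8 were lower, with a median of -1.05. MSMEG_3931, the [NiFe] hydrogenase beta subunit, had -2.54 and -1.51, and MSMEG_3929, the delta subunit, -2.15 and -2.76 (-4.27 to -1.99 with 25% more or less background). Universal stress proteins, 5 of 14 higher and 8 lower (6 and 8 with library totals alone), had 7 of 8 lower and 1 higher after subtraction (camera's adjusted p = 0.0097, and 0.31 with an estimated correlation). This list shares members with the DosR list, including MSMEG_3936, MSMEG_3939, MSMEG_3940, MSMEG_3945 and MSMEG_3950, so the calls of these lists are not independent. MSMEG_3948, an acyltransferase gene in the same region, had -2.78 and -1.90. Camera's adjusted p was 3.7e-06 for the DosR list, 0.011 for the hydrogenases and 0.13 for the universal stress proteins (0.00018 with library totals alone), and with an estimated correlation it was adjusted p = 0.43 for each.

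Single genes outside these lists or in lists that did not pass camera also fell. MSMEG_4290 (glnA), glutamine synthetase, was at 1150 ± 49.2 FPKM with ydeH and 3330 ± 62.5 in the mutant, a log2 fold change of -2.54 (SE 0.14, adjusted p = 9.7e-19) and -1.02 after subtraction. MSMEG_2425 (amt), an ammonium transporter, had -1.91 and -1.31. The GlnR nitrogen limitation list as a whole had 8 of 13 higher and 5 lower (camera's adjusted p = 0.69), and 4 of its 5 testable members were lower after subtraction (camera's adjusted p = 0.04, and 0.21 with an estimated correlation). MSMEG_6759 (glpK), glycerol kinase, had -2.56 and -1.16. MSMEG_1423 (mftC) and MSMEG_1422 (mftB), which act in making the redox cofactor mycofactocin, had -2.79 and -2.75, and -1.51 and -1.40 after subtraction. MSMEG_0965 (mspA) had -2.96 and -1.52. The Msp porin list had 2 of 4 lower and 2 higher, and both testable members were lower after subtraction.

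Genes for mycolic acids, ATP synthase and the cytochrome bcc-aa3 oxidase also fell. Their list medians in the mutant were 760, 521 and 2720 FPKM, and 100% of all genes at 320 FPKM or more there were called lower. The counts of lower members before subtraction therefore do not set these lists apart from other genes of their level. All 12 members of the mycolic acid and fatty acid list were lower, over all genes and over the list alone, 11 of them with library totals alone, and 10 of 12 after subtraction with 1 higher. MSMEG_4327 (kasA), an elongating enzyme of mycolic acid synthesis, was at 2070 ± 98.0 against 6150 ± 118 FPKM, a log2 fold change of -2.58 and -1.03 after subtraction. MSMEG_4326 (acpP) had -2.42 and -0.86, and MSMEG_4328 (kasB) had -2.30 and -0.81. All 8 ATP synthase genes were lower under each of these scalings and after subtraction (median -0.56), with MSMEG_4936 (atpD) at -2.18 and -0.93 and MSMEG_4942 (atpB) at -2.08 and -1.09. Of 7 genes of the cytochrome bcc-aa3 oxidase 6 were lower and 1 higher, with library totals alone too, and all 6 testable members were lower after subtraction (median -0.42). MSMEG_4262 (qcrA) and MSMEG_4263 (qcrB) had -2.11 each and -0.58 after subtraction. The alternative cytochrome bd oxidase list had all 4 genes lower, but 2 lower and 1 higher with library totals alone and 3 higher and 0 lower after subtraction. Camera's adjusted p for these lists ran from 2.6e-05 for the mycolic acid list to 0.032 for cytochrome bd. With an estimated correlation it was adjusted p = 0.43 for the mycolic acid and ATP synthase lists, 0.48 for bcc-aa3 and 0.45 for cytochrome bd.

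In 7 more lists most members were lower. Their list medians in the mutant ran from 80.7 FPKM (arginine synthesis) to 2600 FPKM (heat shock). In each level range from 80 FPKM up, 96.3% to 100% of all genes were called lower. Of 58 ribosomal protein genes 53 were lower and 5 higher (48 and 7 with library totals alone), and after subtraction 30 of 53 were lower and 12 higher, with a median of -0.12. MSMEG_1364 (rplJ) and MSMEG_1365 (rplL) had -2.40 and -2.33, and -0.86 and -0.79 after subtraction. Of 22 aminoacyl-tRNA synthetase genes 21 were lower and 1 higher, but 8 lower and 6 higher with library totals alone, and 9 of 19 lower and 4 higher after subtraction. MSMEG_4189 (cysS) had -1.49 and -0.22. Of 15 heat shock and folding genes 14 were lower (12 with library totals alone), and after subtraction 7 of 14 were lower and 5 higher. MSMEG_0709 (dnaK) had -2.07 and -0.51, and MSMEG_0710 (grpE) had -1.90 and -0.35. In the peroxide, superoxide and thiol defence list 15 of 16 were lower (11 lower and 4 higher with library totals alone), and 11 of 13 after subtraction (median -0.22). MSMEG_3461 (katG), catalase-peroxidase, had -1.81 and -0.79, and MSMEG_3479 (tpx) had -1.93 and -0.47. In the glycopeptidolipid locus, which makes a surface lipid of this species, 26 of 32 were lower and 5 higher (17 and 12 with library totals alone), and 14 of 21 were lower and 4 higher after subtraction. MSMEG_0390, an acyltransferase of the locus, had -2.18 and -2.42 (-3.54 to -1.87 with 25% more or less background). All 8 arginine synthesis genes and all 10 genes of the mce4 sterol uptake locus were lower, but with library totals alone 4 and 6 were higher and 1 and 0 lower. After subtraction 2 of 2 (median -0.66) and 6 of 7 (median -0.34) were lower, with MSMEG_3770 (argG) at -1.57 and -0.77. These 7 lists passed camera with a preset correlation, from adjusted p = 2.3e-12 for ribosomal proteins to 0.0031 for arginine synthesis. With library totals alone the calls of arginine synthesis (adjusted p = 0.1) and mce4 (adjusted p = 0.57) ended. After subtraction those of aminoacyl-tRNA synthetases (adjusted p = 0.28), heat shock (adjusted p = 0.33) and mce4 (adjusted p = 0.1) ended. With 25% more background those of ribosomal proteins (adjusted p = 0.99), peroxide defence (adjusted p = 0.06) and the glycopeptidolipid locus (adjusted p = 0.085) ended too. With quantile normalization those of ribosomal proteins (adjusted p = 0.27), aminoacyl-tRNA synthetases (adjusted p = 0.079), the glycopeptidolipid locus (adjusted p = 0.12) and heat shock (adjusted p = 1) ended. With an estimated correlation each had adjusted p = 0.43 except heat shock, at adjusted p = 0.45.

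**Figure D4:**
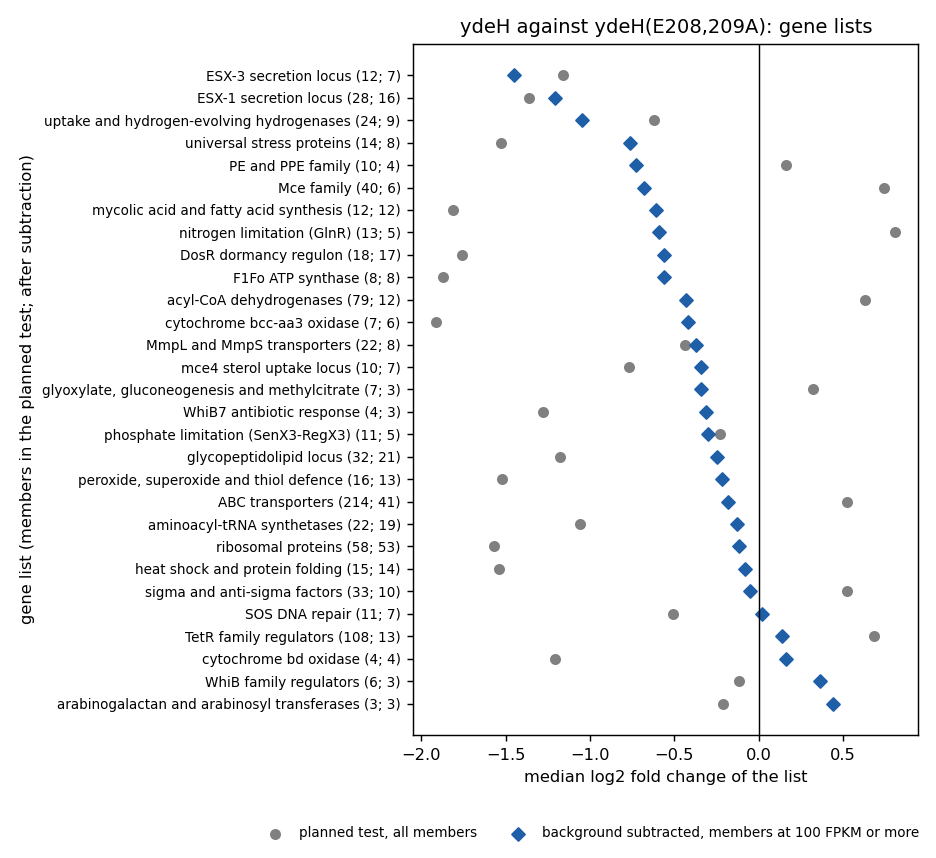
Median log2 fold change of each gene list with at least 3 members testable after subtraction, over all its members in the planned test (grey) and over members at 100 FPKM or more after background subtraction (blue); the 2 numbers beside each name count those members. ESX-3 and ESX-1 lie lowest after subtraction, at -1.45 and -1.21, while cytochrome bd oxidase turns from -1.21 to 0.16 and the Mce family from 0.74 to -0.68. The Mce medians cover 40 members in the planned test and only 6 after subtraction. Without correction in those genes camera's direction of the Mce list did not turn. ESX-3 and ESX-1 had list medians of 122 and 107 FPKM with ydeH, near the fitted background, so their subtracted values depend on its amount.

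The lists that rose held weak genes. Their list medians in the mutant ran from 7.83 FPKM (NADH dehydrogenase) to 24.2 FPKM (TetR regulators). Of all genes at 0 to 10, 10 to 20 and 20 to 40 FPKM in the mutant, 93%, 95.1% and 76.6% were called higher. The counts of higher members therefore do not set these lists apart from other genes of their level. All genes at 0 to 10 FPKM had a median log2 fold change of 1.41, against 1.34 for the NADH dehydrogenase list. All 14 genes of the type I NADH dehydrogenase were higher, with library totals alone too and with 13 of them past the test under median-ratio factors, at list medians of 42.5 FPKM with ydeH and 7.83 in the mutant. MSMEG_2056 (nuoH) was at 42.7 FPKM with ydeH and 7.48 in the mutant, and MSMEG_2061, subunit C, had a log2 fold change of 1.71. Of 34 cytochrome P450 genes 28 were higher and 3 lower (medians 50.2 and 12.1 FPKM), with MSMEG_2240 at 2.28, and both members testable after subtraction were higher. Of 12 genes of the zinc limitation list 10 were higher and 1 lower (75.4 and 14.7 FPKM). MSMEG_6068 (rpmB), a ribosomal protein paralogue of that list, had 2.14. Of 108 TetR family regulators 75 were higher and 19 lower (81.7 and 24.2 FPKM), and of 13 testable after subtraction 5 were higher and 3 lower. Of 79 acyl-CoA dehydrogenase genes 50 were higher and 19 lower, but 10 of the 12 testable after subtraction were lower and 1 higher (camera's adjusted p = 0.0089 as lower, and 0.19 with an estimated correlation). MSMEG_2080 of that list had -2.11 and -0.67. Camera's adjusted p was 3.7e-04 for P450 genes, 0.0013 for NADH dehydrogenase, 0.0028 for TetR regulators, 0.039 for zinc limitation and 0.043 for acyl-CoA dehydrogenases. With an estimated correlation it was adjusted p = 0.43 for the first 4 lists and 0.65 for the last. With library totals alone camera's calls ended for NADH dehydrogenase (adjusted p = 0.064), zinc limitation (adjusted p = 0.14) and acyl-CoA dehydrogenases (adjusted p = 0.14). With quantile normalization they ended for P450 genes (adjusted p = 0.23), TetR regulators (adjusted p = 0.2), NADH dehydrogenase (adjusted p = 0.33) and zinc limitation (adjusted p = 0.52), and after subtraction for TetR regulators (adjusted p = 0.61). The acyl-CoA dehydrogenase call also ended without ydeH replicate 3 (adjusted p = 0.053) or mutant replicate 1 (adjusted p = 0.05). NADH dehydrogenase and zinc limitation genes lay under 100 FPKM on average, so that 0 of them could be tested after subtraction.

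The single genes that rose furthest had the same low levels. They were MSMEG_4409, MSMEG_0723, MSMEG_5974, MSMEG_1309, MSMEG_4443, MSMEG_4445, MSMEG_5950, MSMEG_2147, MSMEG_4080 and MSMEG_2145, with log2 fold changes from 2.58 to 3.93. Most are annotated as hypothetical proteins, and MSMEG_5950 as an acetyltransferase of colanic acid synthesis. Those with a symbol were MSMEG_4418 (msrB) at 2.30, MSMEG_5957 (algD) at 2.24, MSMEG_6068 (rpmB) at 2.14, MSMEG_5983 (rfbA) at 2.10 and MSMEG_4417 (msrA) at 2.09. MSMEG_4417 and MSMEG_4418 encode methionine sulfoxide reductases, which were at 28.2 ± 3.64 and 15.5 ± 3.51 FPKM with ydeH and 3.25 ± 0.831 and 1.52 ± 0.0983 in the mutant. None of these 15 genes reached a mean of 100 FPKM.

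Among genes tied to c-di-GMP, MSMEG_2196, annotated as a sensory box response regulator, was at 96.8 ± 1.73 FPKM with ydeH and 60.8 ± 0.510 in the mutant, a log2 fold change of -0.33 (SE 0.07, adjusted p = 5.8e-05) that turned to 0.67 with library totals alone. MSMEG_2774, annotated as a diguanylate cyclase, was at 86.4 ± 6.63 and 81.6 ± 5.48 FPKM, with -0.92 that turned to 0.08. MSMEG_6479, a transcriptional regulator, was at 126 ± 14.1 and 26.7 ± 4.09 FPKM (1.22, SE 0.12, adjusted p = 1.1e-11). It could not be tested after subtraction, and 76.6% of the 1245 genes at 20 to 40 FPKM in the mutant were called higher. MSMEG_6441, a TetR family regulator, did not pass the test (0.17, SE 0.11, adjusted p = 0.13), and had 1.17 with library totals alone. MSMEG_5244 (dosR), the regulator of the DosR regulon, was at 2440 ± 131 and 3830 ± 22.2 FPKM, with -1.65 (SE 0.12) and -0.10 after subtraction (-0.25 to 0.06 with 25% less or more background, so that its direction turned). The list of 5 had 3 lower and 1 higher, over all genes and over the list alone, but 1 lower and 3 higher with library totals alone, with camera's adjusted p at 0.53.

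The remaining lists did not pass camera with a preset correlation. Higher and lower members numbered 41 and 8 of 77 for transposases and integrases (adjusted p = 0.055), 27 and 4 of 44 for ribosomal and transfer RNA, a sign of RNA preparation, and 15 and 6 of 22 for siderophore and iron genes. They numbered 25 and 13 of 40 for the Mce family, 126 and 72 of 214 for ABC transporters, 18 and 12 of 33 for sigma and anti-sigma factors, and 4 and 3 of 7 for the glyoxylate and gluconeogenesis list. Lists with more lower than higher members were SOS repair (3 higher and 8 lower of 11), MmpL and MmpS transporters (6 and 13 of 22), WhiB7 response (1 and 3 of 4), phosphate limitation (4 and 6 of 11), sterol degradation (3 and 5 of 9), arabinosyl transferases (0 and 2 of 3) and toxin-antitoxin pairs (1 and 3 of 6). With library totals alone more members were higher than lower in these lists, except the WhiB7 response. The WhiB family had 2 higher and 2 lower of 6. After subtraction the Mce family turned to 0 higher and 6 lower of 6 and ABC transporters to 10 higher and 23 lower of 41, and both lists then passed camera as lower (adjusted p = 0.035 and 0.047, and adjusted p = 0.38 and 0.24 with an estimated correlation). Without correction in the same genes camera's direction turned for ABC transporters but not for the Mce family. Its testable members include MSMEG_5899 of mce4, at 123 ± 5.01 FPKM with ydeH and 122 ± 6.69 in the mutant. The subtracted value of MSMEG_5899, -0.68, ran from -1.13 to -0.40 with 25% more or less background. Higher and lower members after subtraction numbered 4 and 4 of 10 for sigma factors, 0 and 3 of 3 for glyoxylate, 2 and 3 of 7 for SOS repair, 2 and 5 of 8 for MmpL and MmpS, 0 and 2 of 3 for WhiB7, 1 and 3 of 5 for phosphate limitation, and 2 and 0 of 3 for both arabinosyl transferases and the WhiB family. Sterol degradation, toxin-antitoxin pairs and ribosomal and transfer RNA had 1 testable member each, which did not pass, and transposases and siderophores had 0. The transposase list passed with median-ratio factors (adjusted p = 0.04), with DESeq2 (adjusted p = 0.04), with no filter (adjusted p = 0.043), and when ydeH replicate 2, ydeH replicate 3 or mutant replicate 3 was left out. With library totals alone the WhiB7 list passed as lower (adjusted p = 0.033). These calls used a preset correlation, and with an estimated correlation in the planned test the lists had adjusted p = 0.43 and 0.45.

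Changed genes lay in runs along the chromosome. There were 538 runs of 4 or more neighbours changed in 1 direction, 292 higher and 246 lower, against a median of 301 and a highest value of 347 in 1000 random gene orders (permutation p = 0.001, the smallest they can give). Direction followed expression level, and random orders break up neighbours of similar level. The excess of runs therefore cannot be told apart from shared levels of neighbours. The longest lower runs were MSMEG_6391 to MSMEG_6418, 28 genes at 6455190 to 6489386 with a median log2 fold change of -0.97, MSMEG_3137 to MSMEG_3152 and MSMEG_3894 to MSMEG_3910, each of 16 genes. The longest higher runs were MSMEG_4850 to MSMEG_4889, 40 genes with a median of 1.23, MSMEG_2869 to MSMEG_2896, 28 genes, and MSMEG_6823 to MSMEG_6847, 25 genes. Runs of genes at least 2-fold lower after subtraction were MSMEG_3936 to MSMEG_3945 (7 tested genes, 4005847 to 4015264, median -1.45), MSMEG_1677 to MSMEG_1683 (6 genes), MSMEG_3929 to MSMEG_3934 (5 genes), and MSMEG_0059 to MSMEG_0062, MSMEG_0065 to MSMEG_0068 and MSMEG_1421 to MSMEG_1424 (4 genes each). The only run at least 2-fold higher after subtraction was MSMEG_6922 to MSMEG_6928, 4 tested genes with log2 fold changes of 1.01 to 1.39. Runs of genes near the background depend on its handling: MSMEG_0062 had -0.79, under 2-fold, with background drawn into the mutant counts.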

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

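The alternatives on background and thinning were chosen after the data were seen. Between 5820 and 6021 genes changed when 1 library was left out, 2803 to 3289 of them at least 2-fold, with 19 to 21 lists and 514 to 536 runs. No filter, a filter at 5 FPKM, robust empirical Bayes, library totals alone, median-ratio factors, DESeq2, limma without quantile normalization and thinning kept total counts of genes, lists and runs within 1.5 times. By direction this did not hold for library totals alone (5221 genes higher and 966 lower, 3732 and 93 at least 2-fold) or for limma without quantile normalization (5259 and 1011, 3695 and 92 on log2(FPKM + 1)). Of 40 lists, library totals alone kept direction and call for 28, ended the call of 5 (acyl-CoA dehydrogenases, arginine synthesis, mce4, NADH dehydrogenase, zinc limitation) and added 2 (universal stress, WhiB7). Limma without quantile normalization ended and added the same calls and kept 26 or 27. Quantile normalization kept 20, ended 8 and added 1 (MmpL and MmpS). Without correction in genes at 100 FPKM or more the calls of aminoacyl-tRNA synthetases, cytochrome bd, the glycopeptidolipid locus, TetR regulators and hydrogenases ended, and with 25% more background those of peroxide defence, the glycopeptidolipid locus, ribosomal proteins, aminoacyl-tRNA synthetases and TetR regulators. The counts at least 2-fold moved to 548 with quantile normalization, 188 with subtraction, 169 and 240 with 25% less and 25% more background, 40 with background drawn into the mutant counts and 185 without correction in the same genes. Changed genes numbered 1658, 1713, 1581, 1596 and 1815 in those 5 settings, and runs 116, 125, 107, 105 and 141, because 2158 genes were tested. Quantile normalization gave 268 runs and 11 lists, 25% less background 13 lists, and no correction 11 lists. Runs of 6 or more genes numbered 299. In every other case the cause was not tested.

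With the replicate number as a block, 5882 genes changed, 3064 of them at least 2-fold, with 20 lists and 519 runs, and the block changed the call of no named gene or list. Deviations of libraries with the same number correlated at 0.08, -0.34 and -0.08, so the numbers do not pair the libraries.

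Directions that turned are given as log2 fold changes for genes. For lists they are the list's mean minus that of other genes where camera's direction turned, and that difference kept its sign in some of them. With library totals alone they were MSMEG_2196 0.67, MSMEG_2774 0.08, whiB1 0.93, rbpA 0.77, mbp1 0.99 and, of lists, arabinosyl transferases -0.32, nitrogen limitation -0.05, phosphate limitation -0.12, sigma factors 0.07, sterol degradation -0.26. With median-ratio factors and with DESeq2, MSMEG_6441 was at -0.01. With limma on log2(FPKM + 1), with or without trend, they were MSMEG_2196 0.66, MSMEG_2774 0.08, whiB1 0.93, rbpA 0.77, mbp1 0.99 and, of lists, arabinosyl transferases -0.28, nitrogen limitation -0.04, phosphate limitation -0.10, sigma factors 0.07, sterol degradation -0.23, toxin-antitoxin pairs -0.20. With a pseudocount of 0.1 they were MSMEG_2196 0.67, MSMEG_2774 0.08, whiB1 0.93, rbpA 0.77, mbp1 1.00 and, of lists, arabinosyl transferases -0.32, nitrogen limitation -0.05, phosphate limitation -0.13, sigma factors 0.06, sterol degradation -0.26, toxin-antitoxin pairs -0.23, transposases 0.62. With a pseudocount of 5 they were MSMEG_2196 0.63, MSMEG_2774 0.08, whiB1 0.92, rbpA 0.76, mbp1 0.98 and, of lists, arabinosyl transferases -0.16, nitrogen limitation -0.02, phosphate limitation -0.05, sigma factors 0.06, sterol degradation -0.14, toxin-antitoxin pairs -0.13, transposases -0.24. With TPM they were MSMEG_2196 0.68, MSMEG_2774 0.10, whiB1 0.95, rbpA 0.78, mbp1 1.01 and, of lists, arabinosyl transferases -0.27, nitrogen limitation -0.03, phosphate limitation -0.10, sigma factors 0.07, sterol degradation -0.22, toxin-antitoxin pairs -0.20. Quantile normalization gave dosR 0.01, whiB1 1.37, rbpA 1.09, mbp1 1.23 and, of lists, ABC transporters -0.16, acyl-CoA dehydrogenases -0.07, arabinosyl transferases 0.35, cytochrome bd 0.16, Mce family -0.14, nitrogen limitation -0.05, phosphate limitation 0.13, ribosomal and transfer RNA 0.06, siderophores -0.06, transposases -0.34, WhiB family 0.58. Without mutant replicate 1 whiB1 and mbp1 were at 0.03 and 0.10, and without ydeH replicate 3 mbp1 was at 0.04. For the turned directions the cause was not tested.

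Background subtraction turned whiB1 1.39, rbpA 1.19, mbp1 1.35 and, of lists, ABC transporters -0.27, acyl-CoA dehydrogenases -0.45, arabinosyl transferases 0.38, cytochrome bd 0.26, Mce family -0.60, nitrogen limitation -0.67, WhiB family 0.60. With 25% less background these were whiB1 1.27, rbpA 1.08, mbp1 1.26 and, of lists, ABC transporters -0.22, acyl-CoA dehydrogenases -0.40, arabinosyl transferases 0.53, cytochrome bd 0.15, Mce family -0.35, nitrogen limitation -0.60, sigma factors -0.06, WhiB family 0.47. With 25% more they were dosR 0.06, whiB1 1.53, rbpA 1.31, mbp1 1.46 and, of lists, ABC transporters -0.31, acyl-CoA dehydrogenases -0.55, arabinosyl transferases 0.19, cytochrome bd 0.44, heat shock 0.17, Mce family -1.03, nitrogen limitation -0.76, WhiB family 0.81. With background drawn into the mutant counts they were whiB1 1.21, rbpA 1.02, mbp1 1.05 and, of lists, ABC transporters -0.16, acyl-CoA dehydrogenases -0.27, arabinosyl transferases 0.17, cytochrome bd 0.20, Mce family -0.28, nitrogen limitation -0.47, WhiB family 0.52. Without correction in the same genes they were whiB1 0.98, rbpA 0.83, mbp1 1.05 and, of lists, ABC transporters -0.11, acyl-CoA dehydrogenases -0.35, arabinosyl transferases 0.81, mce4 0.19, nitrogen limitation -0.48, phosphate limitation 0.13, sigma factors -0.23, WhiB family 0.20. Lists there hold only members at 100 FPKM or more, so part of the turn follows from fewer genes tested. MSMEG_2768 and MSMEG_0416 were not followed over the alternatives. The other genes given with values kept their direction under every alternative that tested them, and of these only rpmB and MSMEG_2061 lost their call, with quantile normalization.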

Other observations

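The patterns below were seen first, and every test of an explanation here was chosen after the result was seen.

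Of the 68 genes at least 2-fold higher after background subtraction, 5 had a mutant level of at least 200 FPKM. MSMEG_1919 (whiB1), an iron-sulfur regulator of the WhiB family, was at 771 ± 25.5 FPKM with ydeH and 406 ± 38.7 in the mutant (SD, n = 3). Its log2 fold change was -0.08 (adjusted p = 0.35 by edgeR's quasi-likelihood test) in the planned test, 1.39 (SE 0.07) after subtraction and 1.21 when the same background was drawn into the mutant counts. MSMEG_3858 (rbpA), an RNA polymerase binding protein, was at 503 ± 47.0 and 295 ± 16.5 FPKM, with -0.23 and 1.19 after subtraction. MSMEG_1770 (mbp1) had -0.02 and 1.35. The other genes at that level were MSMEG_2768 and MSMEG_0416, and all of them were chosen after their values were seen.

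Weakly expressed genes were higher in every ydeH library. In genes at 40 to 400 FPKM in the mutant the fitted excess changed by -8.38 FPKM per Mb from the origin (mean of 3 libraries). In genes under 40 FPKM the ydeH minus mutant difference changed by -0.23 log2 per Mb (SE 0.011). The excess was not even over weak genes. Its median was 27.8 FPKM at 0 to 10 FPKM in the mutant, 47 at 10 to 20 and 56 at 20 to 40. At 0 to 10 FPKM the ydeH median, 34.4 FPKM, lay below the lowest fitted background, 45.4 FPKM at the terminus. An even background of the fitted size therefore does not hold in the weakest genes. The fall with distance is what a background along a replicating chromosome, as from genomic DNA, would give if larger in the ydeH libraries. The difference between mutant libraries 2 and 1 also fell with distance, at -0.59 FPKM per Mb, so a smaller background of this kind may differ within a group. Depth does not account for the increase: after thinning to the smallest total 1821 genes were at least 2-fold higher, 1738 of them among the 1811 found before. Pervasive transcription that follows gene dosage was not separated from genomic DNA here.

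Strongly expressed genes were lower with ydeH. With a background of the fitted size, dilution as the whole cause did not hold. Of 1121 testable genes at least 2-fold lower, 117 were at least 2-fold lower after subtraction, and 90 with 25% less background. Subtraction lowers only the ydeH counts, so it can itself bring genes near the background past 2-fold. When the same genes were tested without correction 74 were at least 2-fold lower, so the fall from 1121 also follows from the choice of genes and their scaling, and the share due to dilution is left open. Of the 120 genes at least 2-fold lower after subtraction, only 47 were among those 74. When the background was instead drawn into the mutant counts, 33 genes were at least 2-fold lower, all of them among the 120 found by subtraction.

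The 68 genes at least 2-fold higher after subtraction had a median length of 484.5 bp, against 832.5 bp of all 2158 tested genes, and 61.8% against 26.7% were annotated as hypothetical. The largest were MSMEG_5098 and MSMEG_2689, both hypothetical, at 2.44 and 2.43. The 68 genes had a median mutant level of 62.7 FPKM, against 200 FPKM in all tested genes. The filter took the mean over both groups, so a gene weak in the mutant passed it only with a high ydeH level. The make-up of the 68 genes therefore follows in part from the filter. The cause of the increase in the 68 genes was not tested.

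Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, reached each of its own counts: 6006 genes changed, 3045 of them at least 2-fold, 20 lists and 538 runs. The highest values in the other splits were 0, 0, 19 (16 to 19 lists) and 0, with at most 3 genes at an unadjusted p under 0.05. Those 10 splits are too few to judge chance.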
